A study of Mus musculus with 209 samples.

How the data were processed

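The series holds 209 samples, of which 54 had columns in the count tables given here. The other 155, labelled as ACE, PBAT, COOL and WGBS assays, were not analysed here. According to the labels, MII oocytes were collected 14 to 15 hours and 2-cell embryos 42 to 43 hours after hCG injection.

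The values of every table are raw counts per gene symbol, as deposited by the authors, with no normalization. One table held the total counts of the oocytes and 2-cell samples, a pair of tables split the same counts into maternal and paternal alleles, and each epiblast group had its own table. The submitters' processing notes list cutadapt 1.15, Trim Galore 0.6.6, STAR 2.6.0a, HTSeq 0.10.0, featureCounts 2.0.1, SAMtools 0.1.18, Bismark 0.23.0, MethylDackel 0.5.0 and build mm9, with no role or order. Of 24542 rows, 92 were ERCC spike-ins and left out of the totals, and 24450 gene rows stayed. In the allele tables all 33 oocyte columns of the maternal table equalled the total table and all 33 of the paternal table were 0, so oocytes were not split by allele. The planned removal of genes with paternal counts in oocytes could therefore not be carried out. In 2-cell samples 37.0% of WT and 39.5% of KO counts were assigned to an allele, and 2046 of 244199 gene and sample values above 0 had more allele counts than total counts. The epiblast tables were joined on 24446 symbols, after 4 rows that shared a name were left out. In them 22 symbols had been turned into dates and were kept but not named. No library was a copy of another: the smallest chi-square per gene between libraries of a group was 14.3.

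Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each oocyte or 2-cell library is a single cell per the labels, with no animal named, so each group was treated as 1 sample, its counts were summed, and no test was run between groups. Genes at 10 CPM or more in either pool were compared by the log2 ratio of pooled CPM with an exact conditional Poisson interval at 95%, and counted as higher or lower at 2-fold or more. A pool at 0 was set to a floor of 3 counts over the group. For each gene list the median ratio was placed among 10000 random lists of the same size, matched in 20 bins of expression. The confidence interval of a share was the exact Clopper-Pearson interval. In simulated counts with known folds, 90, 88 and 86% of 3-fold genes and all 6-fold genes were recovered in the 3 comparisons, while 1.00, 7.65 and 4.16% of unchanged genes reached 2-fold.

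The stage classes were fixed on odd-numbered WT 2-cell samples against all WT oocytes, at 4-fold, and compared between KO and even-numbered WT samples, so that no library served in both steps. The shares of counts that the classes take are given for even-numbered WT samples, and those over all WT samples include libraries that chose the classes. Paternal shares are paternal counts over paternal plus maternal counts, for genes with 50 or more. Oocyte library sets were defined after the data were seen, by spike-in RNA above 0.01% of counts and, among the others, Rn45s under 1%. They are not groups of the study.

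Epiblast counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size over the root of F. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry. The camera p-values were adjusted over 19 lists. Where a group had no count, the bound is against 3 counts over the group, and with 1 to 3 counts the ratio has its counting interval. Such a bound, written as at least, is a ratio with 0 replaced by 3 counts. It is not a confidence limit and leaves out the spread between libraries. On simulated counts with 10800 genes this design recovered 2.27, 25.5, 41.7 and 48.9% of genes changed 4, 16, 64 and 256-fold, with 4 false among 60 calls. The simulation changed far fewer genes than passed in the data, so its adjusted threshold was stricter and these rates do not carry over directly. The deviations of same-numbered replicates correlated at 0.00606, so the numbers were not read as pairs.

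Among oocytes and 2-cell samples, Nlrp14 was named first, then the 10 highest and 10 lowest ratios per comparison. These genes had 20 CPM or more in the higher pool, a count in at least 50% of its libraries, a median over libraries on the same side, and at least 75% of its libraries above the other median. In epiblast they were the 10 highest and 10 lowest past the threshold, with a mean of 10 CPM or more and no overlap of the groups. Predicted gene models were passed over. From each list up to 4 members with the largest ratios could be added, and any member of the DNA methylation list. Paternal shares were given for the 10 zygotic-class genes with the most allele-assigned counts and for the imprinted list. Lists covered DNA methylation and demethylation, ribosomal proteins, ribosome biogenesis, p53 targets, the stress response, oxidative phosphorylation, imprinted genes, NLRP and oocyte transcripts, zygotic genome activation, maternal mRNA decay, calcium handling, the cell cycle, pluripotency, germ layers, germ cells, glycolysis, cholesterol synthesis, oxidative stress, immediate early genes and extracellular matrix. Markers of cumulus and granulosa cells, trophoblast and endoderm stood for other cell types.

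Alternatives were other scalings (TMM, DESeq2 1.42.0 and upper-quartile factors, and spike-in counts), equal weight per cell, medians over cells, other limits on low counts, other tests (DESeq2, limma-voom, glmTreat), a replicate block, thinning of the epiblast libraries, and leaving out each library in turn. No library held under 1/3 of its group's median counts, so that alternative changed nothing, and X and Y genes could not be left out because no mm9 gene positions were at hand. Further work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.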

Results

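RNA was sequenced from 33 single mouse MII oocytes, the stage at which an egg is ovulated, from 17 single 2-cell samples, and from 4 epiblast samples, the embryonic layer that gives rise to the body. The oocytes were 14 wild-type (WT) and 19 knockout (KO), and the 2-cell samples 8 WT and 9 KO. The genotype is labelled N14 maternal KO, read here as Nlrp14, an oocyte gene of the NLRP family which mothers deposit in the egg. The epiblast samples were 2 from cultured embryos (IVC) and 2 from embryos at E6.5, labelled E6.5 ND, where the meaning of ND is not given. Total counts per library ran from 3933604 to 13052327 in WT oocytes, from 4585916 to 10637866 in KO oocytes, from 3788348 to 10303580 in WT 2-cell samples and from 2704050 to 15007301 in KO 2-cell samples. The IVC epiblasts held 10377163 and 10241401 counts, and the E6.5 epiblasts 11826853 and 24047088. The tables name genes by symbol alone, so positions are not given. The oocyte and 2-cell libraries carry no molecular identifiers and no named animal, so each group counts as 1 sample, no test between groups was possible, and intervals cover counting error only.

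Nlrp14 transcripts were scarce in every KO library. In oocytes the pooled level was 36.7 CPM (counts scaled to library totals) in KO and 726 CPM in WT, 19.8 times lower, at a log2 ratio of -4.31 (-4.35 to -4.27). All 19 KO oocytes, at 0.643 to 73.2 CPM, lay below all 14 WT oocytes, at 225 to 3307 CPM. WT oocyte replicate 14 held the 3307 CPM, and without it the ratio was -3.71. In 2-cell samples the ratio was -2.03 (-2.08 to -1.97), with KO at 29.4 to 86.4 CPM and WT at 106 to 477 CPM, again without overlap.

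**Figure D1:**
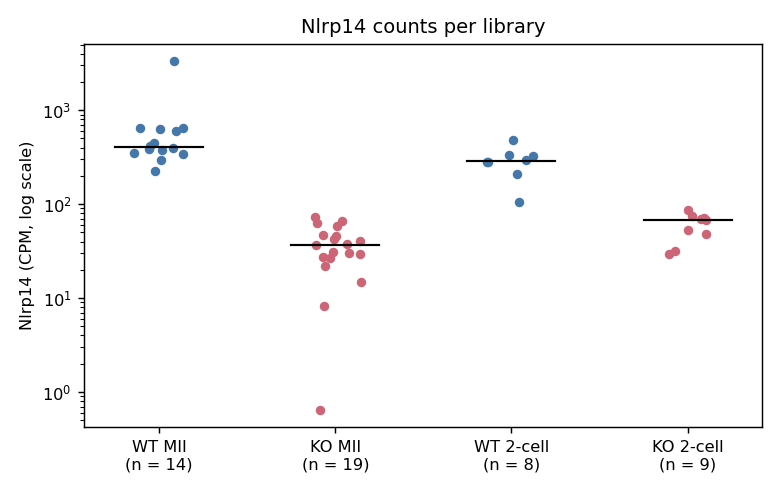
Nlrp14 in each single oocyte and 2-cell library, in CPM on a log axis, with a line at each group's median. The KO oocytes reach 73.2 CPM at most and the WT oocytes start at 225 CPM, while the KO 2-cell samples reach 86.4 CPM and the WT 2-cell samples start at 106 CPM.

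The oocyte comparison asks what the loss of Nlrp14 leaves different in the egg before fertilisation. The pools of all libraries mix the library sets described below unequally, so their counts do not settle how many transcripts differ. Within spike-in libraries alone 600 of 6375 genes were higher and 235 lower, and within low-rRNA libraries 118 and 121 of 5957. In the pools 129 of 6325 genes at 10 CPM or more were at least 2-fold higher and 151 at least 2-fold lower in KO. The median of all genes was 0.02. Higher in KO were Cldn15, a tight junction claudin, at 2.41 (2.26 to 2.55), Tuba1c, an alpha tubulin, at 1.64 (1.57 to 1.71), Cpsf3, the endonuclease that cleaves pre-mRNA before the poly(A) tail is added, at 1.57 (1.47 to 1.68), and Abcg1, a sterol transporter, at 1.53 (2.15 without WT replicate 3). Abcg1 was under 2-fold apart within each library set described below (0.81 with spike-ins, 0.97 with little rRNA, 0.29 in the remaining one). Lower were Ddx60, at -2.11 (-2.22 to -2.01), and Ddx58, at -2.04 (-2.14 to -1.95), both helicases of antiviral RNA sensing, and Msi2, an RNA-binding protein, at -1.93 (-2.05 to -1.82).

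The other genes named in oocytes were Rnf6 (1.78), Rrp36 (1.64), Marveld2 (1.64), Grn (1.53), Tlr8 (1.43) and Zdhhc24 (1.43) on the higher side. On the lower side were Zfp770 (-2.14), Stard5 (-1.88), Zfp281 (-1.76), Krt12 (-1.69), Gstm5 (-1.69) and Nifk (-1.66). For Grn, a lysosomal growth factor precursor, Tlr8, a receptor for RNA in endosomes, and Zdhhc24, each of the 19 KO oocytes lay above the WT median. For Krt12, a keratin, and Gstm5, a glutathione transferase, each lay below it. Without WT replicate 2 the ratio of Grn was 2.23. Some ratios differed between library sets: among low-rRNA libraries Zfp770 was at 0.27, Zfp281 at -0.13, Ddx58 at -0.30, Nifk at -0.45, Gstm5 at -0.53, Marveld2 at 0.48, Tlr8 at 0.70, Grn at 0.78 and Zdhhc24 at 0.88. Among spike-in libraries Ddx58 was at -1.88, Marveld2 at 2.64, Tlr8 at 3.22, Grn at 2.92, Zdhhc24 at 2.05 and Tuba1c at 2.39. In the remaining set of 3 libraries Zfp281 was at 0.24, Tlr8 at -0.13, Cpsf3 at -0.04, Ddx60 at -0.07, Ddx58 at -0.39, Rnf6 at 1.03, Tuba1c at 0.95, Cldn15 at 1.47, Marveld2 at 3.14 and Gstm5 at -2.97.

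Among the fixed gene lists, the cell cycle and DNA replication list had a median of 0.20 in oocytes, at percentile 98.9 of 10000 matched random lists, with 2 of 36 measured members at least 2-fold higher. These were the replication helicase subunits Mcm5 (1.52) and Mcm3 (1.12). Within spike-in libraries the list was at percentile 97.97, and within low-rRNA libraries its median was 0.00, at percentile 67.0. With all libraries no other list lay beyond the central 95% of its random lists. The integrated stress response list, with a median of 0.34 over 8 genes, came nearest, at percentile 97.47 (99.5 within spike-in and 84.9 within low-rRNA libraries), and Atf4, its central transcription factor, was at -0.96 (0.60 within low-rRNA libraries) while the chaperone Hspa5 was at 0.76. Of 14 measured genes of DNA methylation and demethylation, none was 2-fold apart: the median was 0.21 (0.31, at percentile 97.85, without WT replicate 14), and Dnmt3b, a de novo methyltransferase, was at 0.74, Trim28, a corepressor at imprinted loci, at 0.69 (1.08 within spike-in libraries), Uhrf1, the partner of Dnmt1, at 0.55, Tet3, the oocyte dioxygenase of 5-methylcytosine, at 0.41, Dnmt3a at 0.29, Dnmt1, the maintenance methyltransferase, at 0.24, and Dppa3, a protector of maternal methylation, at -0.35. The other members were Mbd4 (0.57), Dnmt3l (0.18), Apex1 (-0.13), Zfp445 (-0.13), Zfp57 (0.11), Usp7 (-0.08) and Setdb1 (0.08).

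Other oocyte lists had few members 2-fold apart. In the NLRP and subcortical maternal complex list only Nlrp14 of 16 genes was 2-fold apart, with a median of 0.17 (percentile 99.9 within low-rRNA libraries) and Khdc3 at 0.90. Oocyte transcripts had a median of 0.00, with 1 of 41 higher, the zona-cleaving protease Astl (1.25), while Plat, a plasminogen activator, was at 0.95. Maternal mRNA decay and translation control had a median of -0.04, with 1 of 34 lower, the decapping enzyme Dcp2 (-1.09). Cytosolic ribosomal proteins had a median of 0.03, with 1 of 35 lower, Rpl41 (-2.70). Calcium handling had a median of 0.10, with 1 of 19 higher, the store sensor Stim2 (1.34). For p53 targets and apoptosis the median was -0.10, with 1 of 8 higher, the nuclease Aen (1.24). For oxidative phosphorylation and mitochondrial upkeep it was -0.11, with 1 of 25 lower, the mitochondrial transcription factor Tfam (-1.49). Imprinted genes had a median of 0.18, with 1 of 7 higher, the receptor Igf2r (1.12). Without WT replicate 3 Igf2r was at 1.74, and without WT replicate 14 Rpl41 was at -1.67. Within the spike-in and low-rRNA libraries Igf2r was under 2-fold apart, at 0.49 and 0.51, and within low-rRNA libraries Rpl41 was at 0.12, Dcp2 at 0.30, Tfam at -0.43, Stim2 at 0.68, Astl at 0.66 and Plat at 0.41. Ribosome biogenesis had a median of 0.15 over 21 genes, 2-cell transcripts of zygotic genome activation 0.09 over 10, and cumulus and granulosa cell markers 0.38 over 3, none with a member 2-fold apart. Within low-rRNA libraries the cumulus list had a median of 0.51, at percentile 99.1, outside its random lists.

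The oocyte libraries fell into sets that the labels do not name, and the sets crossed the genotypes unequally. Libraries with spike-in RNA above 0.01% of counts numbered 10 WT and 7 KO. Those with little spike-in RNA and under 1% of the ribosomal precursor Rn45s numbered 3 WT and 10 KO, and the remaining 1 WT and 2 KO formed another set. Between the spike-in and low-rRNA sets, 2809 genes were at least 2-fold apart in WT alone and 2455 in KO alone. Within the spike-in set 600 genes were higher and 235 lower in KO, of 6375. Within the low-rRNA set 118 were higher and 121 lower, of 5957. In both sets 32 genes were higher and 17 lower, among them Cldn15, Tuba1c, Cpsf3, Mcm5 and Mcm3 on the higher side and Nlrp14, Ddx60, Msi2, Stard5 and Krt12 on the lower. The ratios of both sets correlated across 5463 genes at r = 0.255, and genes are not independent replicates. The count of higher genes was 234, 285, 194 and 228 without WT replicates 1, 2, 3 and 14, and that of lower genes 228 without WT replicate 2.

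The comparison of WT 2-cell samples with WT oocytes asks how transcripts pass from maternal to embryonic. All 8 WT 2-cell libraries fell in the spike-in set, while the WT oocytes mixed 3 sets, so that stage and set are not separate in the pooled ratios, and each was also taken against the 10 spike-in oocytes alone. Genes that the oocyte lacked were abundant at the 2-cell stage. Timd2 was higher by 13.14 (11.59 to 15.42), Folr1, a folate receptor, by 13.11 (10.63 to 18.42), Pramel6 by 13.10 (10.62 to 18.40), Dkkl1 by 12.87 (10.40 to 18.18), Trim43a by 12.79 (11.43 to 14.67), Tex101 by 12.64 (10.16 to 17.95), Rab39 by 12.59 (10.11 to 17.90), Crxos by 12.52 (10.97 to 14.80), Inafm2 by 12.52 (10.04 to 17.82) and Cldn6 by 12.39 (9.91 to 17.69). The oocyte pools held 1 to 4 counts of each, and leaving out a single oocyte moved most of them, such as Folr1 to 11.46 without replicate 6 and Trim43a to 13.74 without replicate 11. On the lower side Pabpn1l, a poly(A)-binding protein of oocytes, was at -4.74 (-4.95 to -4.53), Rgs2, a regulator of G-protein signalling, at -4.47 (-4.53 to -4.42), Psma7, a proteasome subunit, at -4.32 (-4.38 to -4.26) and Dnmt1 at -4.26 (-4.36 to -4.17). The others were Rad51ap2 (-4.65), Ccdc3 (-4.40), Ufl1 (-4.34), Pde6b (-4.26), Ccdc191 (-4.22) and Gpatch1 (-4.10). Without WT 2-cell replicate 8 Ufl1 was at -5.19 and Gpatch1 at -4.82, without replicate 1 Pde6b at -5.76 and without replicate 6 Rad51ap2 at -5.75. Against spike-in oocytes alone the fall was smaller for Pabpn1l (-2.07, with 18.7 CPM in spike-in and 274 CPM in low-rRNA WT oocytes), Pde6b (-1.64) and Gpatch1 (-3.18). The other 7 lower genes then ran from -4.88 to -4.05, and the 10 higher ones from 10.26 to 13.98.

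Of 8532 genes, 3507 were at least 2-fold higher and 1224 at least 2-fold lower at the 2-cell stage, so that 74.1% of the genes apart were higher, with a median of 0.64. Scaling by TMM moved all ratios by -0.91, which gave 2249 higher and 2758 lower genes, or 44.9% higher. DESeq2 factors moved them by -1.01, which gave 2171 and 2927, or 42.6% higher. Against spike-in oocytes alone 3573 genes were higher and 1084 lower, of which 3156 and 901 were among those above.

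Zygotic genome activation transcripts had a stage median of 6.69, with 31 of 37 higher and 1 lower, including Obox6 (12.07) and Ubtfl1 (11.98). Cytosolic ribosomal proteins had a median of 3.76, with 76 of 82 higher, such as Rps19 (7.71) and Rpl9 (7.53). The p53 list had 10 of 16 higher with a median of 2.91, including Gadd45b (7.06), which acts in growth arrest after DNA damage. These medians stood at percentiles 100, 100 and 99.96 of their random lists. Oocyte transcripts had a median of -0.73, with 20 of 43 lower and 4 higher, and the pooled ratios were lowest for the meiotic kinase Mos (-6.20), Plat (-4.49) and the oocyte linker histone H1foo (-3.71). The NLRP list had a median of -0.99, with 8 of 16 lower and 1 higher, including Nlrp4b (-3.32) and Padi6 (-3.23). These medians stood at percentiles 0.05 and 0.70, and all 5 directions held with TMM and DESeq2 scaling. Without WT 2-cell replicate 8 Mos was at -7.35, Plat at -5.49 and H1foo at -5.92, without WT oocyte replicate 14 Rps19 was at 9.45 and Rpl9 at 9.59, without oocyte replicate 11 Ubtfl1 at 12.93, and without oocyte replicate 2 the rise of Gadd45b was 3.81 times as large on the unlogged scale.

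Part of these stage values depended on the library set. Against spike-in oocytes alone Mos was at 0.89 and Plat at 1.53, both higher at the 2-cell stage: Mos held 1.69 CPM in spike-in, 506 CPM in low-rRNA and 806 CPM in the remaining WT oocytes and 3.15 CPM in WT 2-cell samples, and Plat 18.2, 2704, 3587 and 52.6 CPM. H1foo was then at -2.41, Padi6 at -2.53, Rps19 at 8.84, Rpl9 at 8.97 and Gadd45b, with 1 count in those oocytes, at 10.02. The medians of oocyte transcripts (-0.34, percentile 5.33) and of the NLRP list (-0.58, percentile 4.27) lay within their random lists in that comparison, so their fall was not set apart from other genes there. The lists of zygotic genome activation (6.79), ribosomal proteins (3.96) and p53 targets (2.54) stayed outside theirs.

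The DNA methylation list had a stage median of -0.25, with 6 of 18 genes higher and 3 lower. TMM scaling moved this median, like all stage ratios, by -0.91, so these counts belong to total-count scaling. Higher were Uhrf2 (4.33), the repair endonuclease Apex1 (1.99), Dnmt3l, the cofactor of de novo methylation (1.73), Tet1 (1.73), Mbd2 (1.37) and Tet2 (1.14). Lower were Dnmt1, Dnmt3a (-1.15) and the histone methyltransferase Setdb1 (-1.05). Between these limits were Zfp57 (-0.98), Dppa3 (-0.95), Mbd4 (-0.88), Uhrf1 (-0.58), Trim28 (0.43), Tet3 (-0.37), Usp7 (-0.28), Dnmt3b (-0.21) and Zfp445 (0.12). Without WT 2-cell replicate 8 Zfp57 was at -2.12. Against spike-in oocytes alone the median was 0.19, Dnmt3b was at 0.84, Tet3 at 0.02, Trim28 at 1.04, Mbd2 at 0.99 and Dnmt3a at -0.73.

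The remaining lists lay within the central 95% of their random lists at this stage step when all libraries were pooled. The stress response list had 10 of 17 higher, with a median of 1.98 and the serine synthesis enzyme Psat1 at 9.19 (9.95 without oocyte replicate 14, and moved by more than 1.5 times without replicate 11 too). Imprinted genes had 10 of 16 higher, with a median of 2.20. Nnat, an imprinted gene of the nervous system, was among them, and Jade1 was at 9.43. The cumulus list had 3 of 6 higher and 2 lower, with a median of 2.76. Oxidative phosphorylation had 22 of 42 higher and 2 lower, with a median of 1.10 and cytochrome c1 (Cyc1) at 5.54 (6.47 without oocyte replicate 7, 4.92 against spike-in oocytes). Ribosome biogenesis had 15 of 31 higher and 3 lower, with a median of 0.81, calcium handling 6 of 22 higher and 5 lower (0.54), the cell cycle list 12 of 43 higher and 11 lower (0.33), and maternal mRNA decay 11 of 40 higher and 9 lower (0.13). With TMM scaling these last 4 medians turned negative, at -0.11, -0.38, -0.58 and -0.78. Some of these lists left the range of random lists in other settings. Without WT 2-cell replicate 8 imprinted genes had a median of 3.14 (percentile 97.54) and ribosome biogenesis 1.35 (97.9). Against spike-in oocytes alone imprinted genes were at 3.09 (99.1), ribosome biogenesis at 1.48 (99.3), the stress response at 2.57 (98.6) and cumulus markers at 5.03 (99.6).

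At the 2-cell stage, Nlrp14 KO samples held less of the transcripts that embryos switch on and more of those that oocytes store. Lowest were Inafm2, at -7.01 (-7.63 to -6.46), Zfp280c, at -6.82 (-7.37 to -6.32), the kinase Lck, at -6.26 (-6.90 to -5.68), Arg1, an arginase, at -5.83 (-6.19 to -5.49), and Smad7, an inhibitor of TGF-beta signalling, at -5.64 (-6.02 to -5.29). For each of them all 9 KO samples lay below the WT median. Higher were Mos, which holds the oocyte at metaphase, at 3.66 (3.41 to 3.92), H1foo, at 3.42 (3.40 to 3.43), Zar1, a regulator of stored maternal mRNA, at 2.75 (2.69 to 2.81), and Plat, at 2.48 (2.42 to 2.55). For these 4 genes all 9 KO samples lay above the WT median. Their size rested on single samples: without KO replicate 4 Mos was at 1.51, H1foo at 2.71, Zar1 at 1.76 and Plat at 1.34, and without WT replicate 8 they were at 4.81, 5.63, 3.91 and 3.49. Without KO replicate 1 Zfp280c was at -9.42, and without KO replicate 3 Arg1 at -6.43. How much Mos and Plat was measured in WT oocytes depended on the library set. In the pool of spike-in WT oocytes, given above, both were scarcer than in every KO 2-cell sample (from 1.85 CPM for Mos and 57.2 CPM for Plat). Within that set these values do not show them as transcripts kept from the oocyte.

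The other named genes on the lower side were Iqub (-6.38), Unc119b (-6.14), Tor1b (-5.78), Hsd17b14 (-5.58) and Stmn3 (-5.41). On the higher side were Cryl1 (3.75), Kcnn2 (3.08), Cxcr3 (2.52), Bin2 (2.35), Astl (2.27) and Pinx1 (2.20). Without KO replicate 4 Cryl1 was at 2.90, Bin2 at 1.43, Pinx1 at 1.60 and Hsd17b14 at -6.61, without WT replicate 8 Cryl1 was at 4.74, Kcnn2 at 3.67, Cxcr3 at 5.14, Bin2 at 3.17 and Astl at 3.23, without KO replicate 1 Iqub at -7.08 and without KO replicate 5 Unc119b at -6.99. Of 8416 genes, 502 were at least 2-fold higher and 2658 at least 2-fold lower in KO 2-cell samples, so that 15.9% of the genes apart were higher, with a median of -0.35. TMM moved all ratios by 0.46, which gave 1397 higher and 1916 lower genes (42.2% higher), and DESeq2 by 0.50, which gave 1520 and 1854 (45.1%). Scaled to spike-in counts, 2493 were higher and 1454 lower (63.2%). WT replicate 8 stood apart from the other WT samples, and without it 981 genes were higher.

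Genes of protein synthesis were lower together in KO 2-cell samples. Of 82 cytosolic ribosomal protein genes 74 were at least 2-fold lower and none higher, with a median of -2.24 (-2.48 to -1.99), below all 10000 random lists, and Rpl39 was at -4.18, Rpl38 at -3.93 and Rpl36al at -3.70. Of 30 ribosome biogenesis genes 23 were lower and none higher, with a median of -1.74, below all random lists, and the assembly factors Nop16 and Wdr12 were at -5.35 and -4.89 (-5.53 for Wdr12 without KO replicate 8). Of 42 genes of oxidative phosphorylation 20 were lower and 1 higher, with a median of -0.86, at percentile 1.10 of random lists, and Atp5j was at -3.18 and Cox7c at -3.16. The p53 list had 9 of 16 lower, with a median of -1.13, at percentile 1.46 (6.41, within its random lists, by medians over samples), including Pmaip1 (-2.30) and the cell cycle inhibitor Cdkn1a (-2.11). Imprinted genes had 11 of 16 lower, with a median of -1.89, at percentile 0.22, including Phlda2 (-3.15, and -3.76 without KO replicate 4), which limits placental growth, and the cell cycle inhibitor Cdkn1c (-2.92). These 5 directions held with TMM, DESeq2 and spike-in scaling, although the oxidative phosphorylation median was -0.04 with the last. Of the ribosomal protein genes, 76 of 82 had also risen between stages in WT, and random lists were matched on expression alone. The zygotic class described below had a median of -1.81. Fewer ribosome biogenesis genes had risen, 15 of 31. The class was compared with the even-numbered WT samples and the lists with all WT samples. Whether either list is set apart from other zygotic transcripts was therefore not tested.

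Maternal groups were higher in KO 2-cell samples. The NLRP list had 8 of 16 genes higher and 1 lower, with a median of 0.97, above all random lists, and Nlrp4b was at 1.72, Nlrp5, a core protein of the subcortical maternal complex, at 1.58 and Nlrp4a at 1.54. Its median was 1.54 without WT replicate 8, where Nlrp4a was at 2.27, and Nlrp5 was at 0.83 without KO replicate 4. Oocyte transcripts had 17 of 43 higher and 1 lower, with a median of 0.59, at percentile 99.99. Both directions held with every scaling.

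Transcripts of zygotic genome activation lay on both sides in KO 2-cell samples. Of 38 measured 14 were lower and 2 higher, with a median of -0.54, within the range of random lists, although by medians over samples it was -0.73, at percentile 1.84 and so outside it. Tdpoz2 (-4.50), the homeobox gene Obox6 (-4.41), Dppa4 (-3.62) and Tdpoz4 (-3.25) were lowest, with Tdpoz2 at -7.46 and Tdpoz4 at -3.97 without KO replicate 3. With spike-in scaling this median was 0.28. The DNA methylation list had 2 of 18 genes higher, Uhrf1 (1.43) and the imprint-binding factor Zfp57 (1.02, and 2.17 without WT replicate 8), and 2 lower, Uhrf2 (-1.95) and Apex1 (-1.53), with a median of -0.14, or 0.32 with TMM. Its other members were Dppa3 (0.88), Tet3 (0.81), Tet1 (-0.78), Mbd2 (-0.52), Usp7 (-0.34), Setdb1 (0.28), Zfp445 (-0.22), Mbd4 (0.22), Tet2 (-0.21), Dnmt1 (0.17), Dnmt3l (-0.16), Trim28 (-0.15), Dnmt3a (-0.14) and Dnmt3b (0.07).

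The remaining lists lay within the central 95% of random lists in the KO 2-cell comparison. Maternal mRNA decay had 6 of 40 higher and 10 lower (median 0.05), with the helicase Ddx6 at -3.55. Calcium handling had 1 of 22 higher and 5 lower (0.02), with the calmodulin gene Calm2 at -2.14. TMM moved the medians of both lists up by 0.46, so these counts belong to total-count scaling. The cell cycle list had 6 of 44 higher and 12 lower (-0.09), with Cdk2 at -2.29, and a median of 0.37 with TMM. The stress response list had 1 of 17 higher and 6 lower (-0.46), with Nupr1 at -4.22 (-5.41 without KO replicate 4), and its median was 0.36 with spike-in scaling. Cumulus and granulosa markers had 2 of 6 higher and 3 lower (-1.07), with the gap junction gene Gja1 at -3.21.

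**Figure D2:**
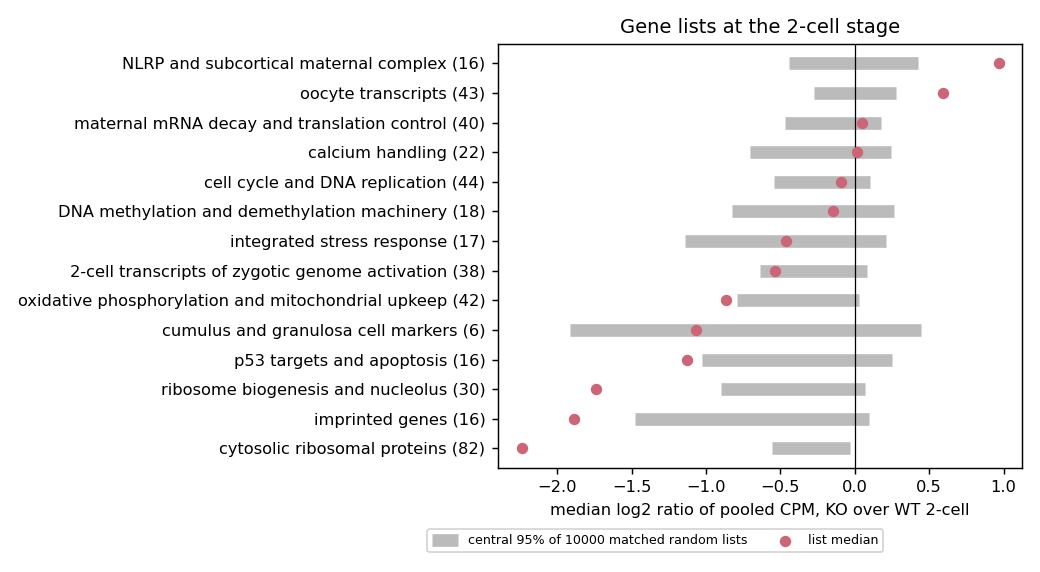
Median log2 ratio of each gene list, KO over WT 2-cell samples, with the central 95% of 10000 matched random lists and the number of measured genes in brackets. Cytosolic ribosomal proteins lie at -2.24 and the NLRP and subcortical maternal complex list at 0.97, both outside their random lists.

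Genes were also classed by the stage step in WT, with no choice by hand. The zygotic class, 2389 genes at least 4-fold higher in odd-numbered WT 2-cell samples than in WT oocytes, was compared between KO and the even-numbered WT samples. Its 2066 measured genes had a median of -1.81 (-1.87 to -1.75), where matched random lists spanned -0.55 to -0.45, with 1620 genes lower and 5 higher. The decay class, 504 genes at least 4-fold lower, had a median of 0.74 (0.68 to 0.82) over 396 measured genes, with 130 higher and 8 lower. Zygotic-class genes took 17.3% of counts in the median of the 4 even-numbered WT 2-cell samples (5.76 to 21.9%) and 4.82% in the median KO sample (3.03 to 11.4%). Decay-class genes took 2.75% (2.40 to 6.67%) and 7.40% (3.70 to 13.03%). Over all 8 WT samples, of which the odd-numbered ones had chosen the classes, the medians were 16.9 and 2.55%. In oocytes, where the WT libraries had also served to choose the classes, the zygotic class took 1.49% in WT and 1.54% in KO, and the decay class 16.7% and 19.7%. Without WT replicate 8 the class medians were -2.41 and 1.29, and with classes chosen against spike-in oocytes alone -1.80 and 0.77.

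**Figure D3:**
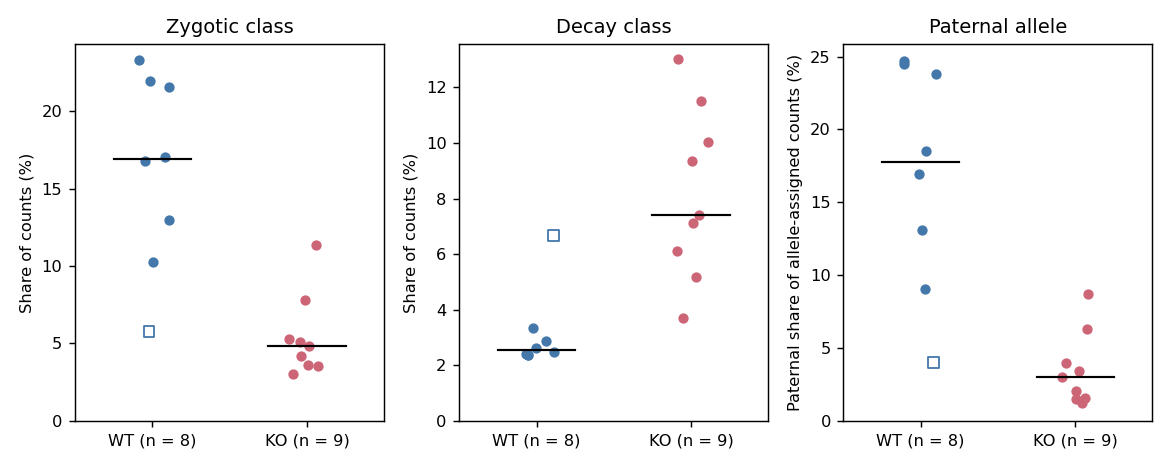
Zygotic-class share, decay-class share and paternal share of counts in each 2-cell library, in percent, with a line at each group's median and WT replicate 8 as an open square. All 8 WT samples are drawn, of which the odd-numbered ones served to choose the classes. The median zygotic-class share is 16.9% in WT and 4.82% in KO, and WT replicate 8 lies at 5.76%.

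Paternal alleles gave a smaller share of the allele-assigned counts in KO 2-cell samples. It was 14.6% (exact interval 14.57 to 14.60) in the WT pool and 2.79% (2.788 to 2.801) in the KO pool, with samples at 4.00 to 24.7% and 1.21 to 8.68%. Without WT replicate 8 the WT share was 18.2%. Within the zygotic class the share was 40.7% in WT and 22.2% in KO, within the decay class 7.19 and 0.858%, and within oocyte transcripts, which the sperm does not supply, 0.620 and 0.204%. For the 804 zygotic-class genes under 1 CPM in oocytes it was 48.4% in WT (samples 47.6 to 49.3%) and 42.4% in KO (38.0 to 45.05%), without overlap. In the even-numbered WT samples, which had no part in choosing the class, these shares were 39.6% for the zygotic class, 5.48% for the decay class and 48.3% (47.9 to 48.7%) for the quiet genes. The oocyte columns were not split by allele, so the background of allele assignment could not be measured in them.

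Among the 10 zygotic-class genes with the most allele-assigned counts, the paternal share was lower in KO for each. It was 47.4 against 44.5% for Dnajb9, a chaperone of the endoplasmic reticulum, 38.9 against 35.0% for the ribosomal stalk gene Rplp0, 49.6 against 36.1% for Calm2, 61.8 against 34.1% for H2afz, a histone variant, 46.5 against 25.0% for Set, 45.6 against 8.75% for Tmed5, 39.6 against 6.29% for Tmem41b, 19.5 against 2.63% for Mier3, 18.96 against 5.29% for Prps1 and 2.18 against 0.637% for Tram1, WT first. Among imprinted genes that are expressed from the paternal allele, shares in WT ran from 96.7 to 2.13%. Zrsr1 was at 96.7% in WT and 61.2% in KO, the noncoding RNA Kcnq1ot1 at 93.2 and 79.0%, Jade1 at 86.6 and 95.6%, Zdbf2 at 82.7 and 9.09%, Impact at 80.3 and 21.4%, Plagl1 at 70.4 and 29.8%, Gab1 at 62.4 and 14.0%, Inpp5f at 49.5 and 9.05%, Airn at 49.5 and 23.4% and Usp29 at 42.5 and 6.45%. Peg3 was at 15.2 and 36.5%, Snrpn at 12.6 and 8.16% and Mest at 2.13 and 0.116%. For Phlda2 the values were 48.8 and 8.92%, for Grb10 15.1 and 3.66%, for Meg3 10.1 and 5.56%, for H13 6.21 and 0.438% and for Gnas 5.09 and 2.13%.

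Epiblast from cultured embryos was compared with epiblast at E6.5. The labels give no embryonic day for IVC, so stage may differ as well, and the shares of Rn45s given below differed between the groups. Among the largest rises were genes of the prolactin and pregnancy-specific glycoprotein families, for which no list was fixed, and Prl2c2, Prl3b1, Prl6a1 and Prl7b1 were not among the tested genes. Against a floor of 3 counts over the group, Prl7a1 rose at least 34023-fold in IVC, Prl2a1 at least 3148-fold, Psg29 at least 3080-fold, Prl5a1 at least 1696-fold and Prl4a1 at least 850-fold. Here and below, such bounds are ratios with 0 replaced by 3 counts, not confidence limits. The calcium-binding S100g rose at least 2326-fold, the lectin Lgals2 at least 2100-fold, Pfpl at least 825-fold and the fatty acid carrier Fabp1 at least 798-fold, and Cystm1, with 1 count at E6.5, by 12.88 (10.40 to 18.18). Genes without a count in IVC included replication-dependent histones: Hist1h3e was at least 2035-fold lower, Hist1h1a at least 1892-fold, Hist1h2bg at least 1175-fold, and Hist1h4a at least 1168-fold lower. They also included the coactivator Yap1, at least 1820-fold lower, the arginine methyltransferase Carm1 at least 1384-fold, the separase Espl1 at least 1095-fold, Srebf2, the activator of cholesterol genes, at least 1058-fold, Plxnb2 at least 1029-fold and the heat shock gene Hspa1b at least 848-fold. With only 1 E6.5 library left, some of these genes missed the threshold. Prl4a1 did so without E6.5 replicate 1 and without replicate 2 (adjusted p = 0.105, 0.115), as did Pfpl (0.0851, 0.0925) and Fabp1 (0.0906, 0.0979). Their fitted ratios hardly moved, at 12.87 and 12.38 for Prl4a1, 12.83 and 12.34 for Pfpl and 12.78 and 12.30 for Fabp1, against 12.87, 12.83 and 12.78 with all libraries. Hspa1b missed it without replicate 1 (0.585), where its ratio was -11.79 against -14.50, and Hist1h4a without replicate 2 (0.0932), at -13.04 against -14.23.

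Of 11565 genes tested with edgeR, 1389 rose and 2717 fell in IVC at an adjusted p under 0.05, and 5244 passed at an unadjusted p under 0.05. The median of all genes was -0.85, and 8565 genes did not overlap between the groups, where chance gives 33.3% of genes. Group and table came together here, each group has 2 libraries, and nothing in the labels says whether replicates are separate embryos or cultures. Without E6.5 replicate 1 the counts were 612 and 125, without E6.5 replicate 2 648 and 118, without IVC replicate 1 2880 and 4997, and without IVC replicate 2 2863 and 5476.

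Of the DNA methylation machinery, 8 of 21 tested genes were lower in cultured epiblast and 1 higher, and 12 were not past the threshold. Adjusted over the list alone, 10 passed it. Among all 11565 tested genes 2717 were lower and 1389 higher. Culture and library protocol cannot be told apart here, and the calls of these genes were not followed with single libraries left out. Dnmt3b, the main de novo methyltransferase of the epiblast, fell by 2.84 on the log2 scale (SE 0.16, adjusted p = 0.0048, n = 2 each), Dnmt1 by 3.22 (SE 0.25, adjusted p = 0.00775), Tet1, which oxidises 5-methylcytosine, by 2.73 (SE 0.26, adjusted p = 0.0123), Uhrf1 by 2.00 (SE 0.36, adjusted p = 0.0398) and Trim28 by 3.77 (SE 0.57, adjusted p = 0.0301). Usp7 fell by 1.77, and Mbd1 and Dnmt3l, with no count in IVC, were at least 101-fold and 51.2-fold lower. Apex1 rose by 1.18 (SE 0.20, adjusted p = 0.0367). Among those not past the threshold were Dnmt3a, at -0.32 (SE 0.18), Tet2 (-0.32), Tet3 (-5.56, SE 2.27), Uhrf2 (-5.86, SE 2.22), Mbd2 (-1.82), Mbd4 (1.43), Setdb1 (-1.14), Mbd3 (-0.77), Zfp57 (-0.76) and Zfp445 (-0.13), and Tdg, with 1 count in IVC, at -4.67 (-10.00 to -2.13). As a set the list, with a median of -1.82, was not set apart from other genes (camera adjusted p = 0.183).

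**Figure D4:**
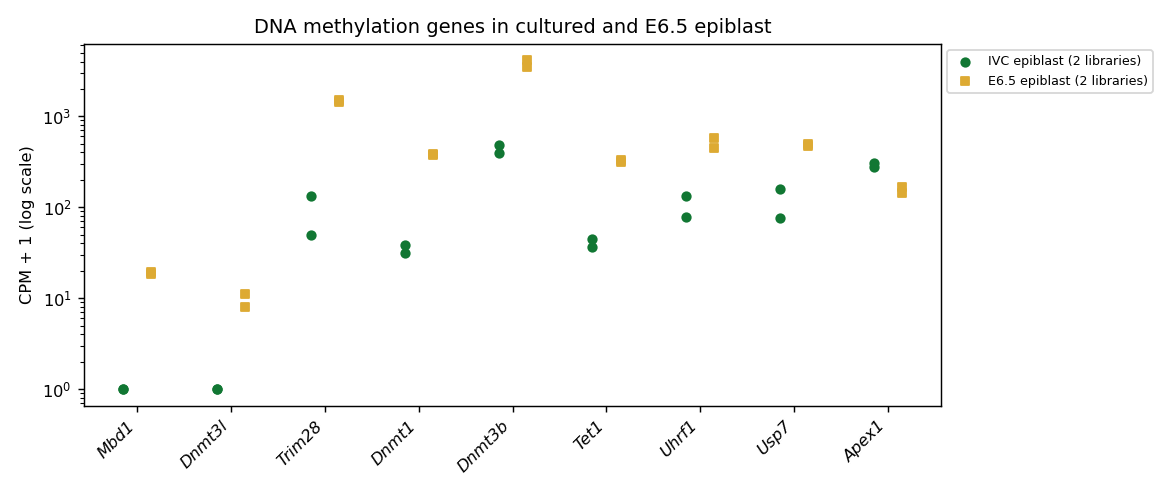
CPM, with 1 added and on a log axis, of the 9 genes of the DNA methylation list past the threshold, in each of the 4 epiblast libraries, ordered by log2 fold change. Dnmt3b lies at 479 and 396 CPM in IVC and at 3508 and 4110.4 CPM at E6.5.

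Genes of protein synthesis and respiration rose in cultured epiblast, where culture and library protocol cannot be told apart. Gene length was not checked, as no gene annotation was at hand. Of 85 cytosolic ribosomal protein genes 71 rose and none fell (75 adjusted over the list alone), with a median of 2.49 and Rps27l at 5.96, Rpl38 at 5.05 and Rpl35 at 4.75. The list passed camera (adjusted p = 2.63e-34), and had adjusted p = 0.364 with an estimated correlation. Of 43 genes of oxidative phosphorylation 29 rose and 3 fell (33 over the list alone), with a median of 3.58, Atp5j at 6.28 and Ndufa1 at 6.75, while the fusion factor Mfn1 had no count in IVC. That list too passed camera (adjusted p = 1.17e-09), and had adjusted p = 0.364 with an estimated correlation. No other list passed camera, and camera with an estimated correlation passed 0 lists, of which 2 had an unadjusted p under 0.05, while fry passed 16. Without either IVC replicate 8 lists passed, adding DNA methylation (adjusted p = 0.00147, 0.0157), core pluripotency (0.0384, 0.0227), glycolysis (0.0251, 0.0157), metallothionein (0.00163, 0.00758), immediate early (0.0366, 0.0157) and matrix genes (0.0115, 0.00391). Without E6.5 replicate 2 4 passed, adding trophoblast (0.00948) and immediate early genes (0.00355).

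Lineage genes of the embryo went both ways in cultured epiblast, most were not past the threshold, and with all libraries none of these lists passed camera. Naive pluripotency genes had 6 of 15 lower and 1 higher (7 adjusted over the list alone; median -1.44), with Klf2 at least 98.6-fold, Fgf4 at least 76.6-fold and Tfcp2l1 at least 38.1-fold lower. Core and formative or primed pluripotency genes had 6 of 30 lower and 2 higher (7; -1.01), with Sox3 at least 219-fold lower and Lin28a, an inhibitor of let-7 processing, at -3.26. Primitive streak and mesoderm genes had 5 of 14 lower and 1 higher (6; -1.97), including Lhx1, at least 69.8-fold, and Mesp1, at least 50.2-fold. Neural and definitive ectoderm genes had 2 of 3 lower (2; -3.33 with genes at 0 set to their bound), namely Nes, at least 307-fold, and Pax6. Primordial germ cell genes had 2 of 7 lower, Alpl and Ddx4, and 1 higher, Ifitm1 (4.01; 3 over the list alone). Imprinted genes had 7 of 30 lower and 2 higher (8; -1.10), and Xist, the RNA of X inactivation, fell by 5.92.

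Markers of extraembryonic tissue went both ways. Of 17 trophoblast genes 6 rose and 3 fell (9 adjusted over the list alone; median 0.31), with Prl3d1, a placental lactogen, at 6254 and 6259 CPM in IVC against 0 and 4.62 CPM at E6.5, and Ascl2 without a count in IVC. Summed, the list took 7652 and 7619 CPM in IVC and 409 and 446 CPM at E6.5. Of its 25 members 14 also reached 1 CPM in both E6.5 libraries, and 7 stand in another list. Of 29 endoderm genes 8 rose and 6 fell (14; 0.98), with Rbp4, a retinol carrier, at 8.10 and Spink1 at 7.83, and the list summed to 2293 and 2925 CPM in IVC against 2895 and 2156 CPM at E6.5.

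Metabolic and stress genes followed in smaller numbers. Glycolysis and hypoxia genes had 12 of 30 lower and 3 higher (18 adjusted over the list alone; median -1.15), with the hexokinase Hk1 at least 127-fold lower. Immediate early genes had 8 of 21 lower and none higher (8; -3.28), with Nr4a1 at least 171-fold lower. Extracellular matrix genes had 11 of 28 lower and 1 higher (12; -2.38), with the laminin chain Lama5 at -5.81. Metallothionein and oxidative stress genes had 6 of 20 higher and 2 lower (8; 0.20), with Mt2 at 5.31, Mt1 at 4.70 and Sod1 at 4.22. Cholesterol synthesis had 4 of 24 higher and 3 lower (7; -0.34), with Pmvk at 3.74. Ribosome biogenesis had 10 of 34 higher and 2 lower (15; -0.14), with Nop10 at 4.28 and Nhp2 at 3.79. The p53 list had 2 of 23 higher and 3 lower (3; -0.54), with the cell death gene Bax at 3.45 and Zmat3 at -3.13, and the stress response list 3 of 24 higher and 1 lower (1; -0.09), with Slc7a5 at -3.24. For the last 3 lists and cholesterol synthesis, camera's direction was up while median and mean were negative, and for primordial germ cell genes the median was 1.65 and the mean -1.62.

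The epiblast libraries differed in more than these groups. Rn45s took 0.101 and 0.121% of counts in IVC and 26.2 and 23.3% at E6.5. Genes detected numbered 8380 and 8990 in IVC and 13101 and 13698 at E6.5, and 2037 tested genes had no count in IVC against 47 at E6.5. Log CPM correlated across genes at 0.686 between the IVC replicates, 0.912 between the E6.5 replicates and 0.421 to 0.447 between groups.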

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

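Tests of library set, dilution, paternal genome, histone genes and Rn45s were chosen after the result was seen, while those of sequencing depth and of few starting molecules in epiblast were written before their values were seen.

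WT 2-cell replicate 8 resembled the KO samples in several measures. Decay-class genes took 6.67% of its counts, against 2.36 to 3.33% in the other WT 2-cell samples (2.40 to 2.87% in the even-numbered ones, which did not choose the class), and spike-ins 0.0583%, against 0.101 to 0.135%. Its NLRP list summed to 42646 CPM (others 4314 to 15839), its DNA methylation list to 7116 CPM (3719 to 4704) and its calcium list to 4102 CPM (5610 to 6762). It held the most Cryl1 (18.1 CPM), Mos (8.64 CPM), H1foo (1786 CPM), Zar1 (140.1 CPM), Cxcr3 (35.8 CPM), Plat (135.9 CPM) and Bin2 (31.6 CPM) of the WT 2-cell samples. Its Nlrp14 level, 106 CPM, stayed above every KO sample, and for zygotic-class genes quiet in oocytes its paternal share was 48.2%, within the range of the other WT samples.

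KO 2-cell replicate 4 stood highest among KO samples for oxidative phosphorylation (3458 CPM, others 2124 to 2515) and for Cryl1 (226 CPM), Mos (136.9 CPM), H1foo (12127 CPM), Zar1 (881 CPM), Plat (802 CPM), Bin2 (169 CPM), Astl (70.7 CPM) and Hsd17b14 (1.80 CPM). KO replicate 3 stood highest for the paternal share of oocyte transcripts (0.510%, others 0.114 to 0.309%), Arg1 (9.62 CPM) and Smad7 (5.18 CPM), and KO replicate 1 for Zfp280c (8.40 CPM). These were 25 of 90 measures in which a sample lay far from its group. Chance would give about 4.5 only for normally distributed measures. Many of these were CPM of genes named for their large ratios in the same samples.

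Cpsf3 lay higher in every KO oocyte than the WT median (1.57) and lower in every KO 2-cell sample (-0.71), a difference between stages that was not tested, and 78 genes showed such a reversal. With spike-in scaling its 2-cell ratio was 0.12, which ends the reversal, with TMM it was -0.25, and in the smallest oocyte set its ratio was -0.04. Spike-in RNA, which the comparisons leave out, gave 1.77 times as many gene counts per spike-in count in KO as in WT 2-cell samples (1745 and 986 over the pooled samples).

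A first pattern is the set of genes 2-fold apart between KO and WT oocytes. The library sets cross the genotypes unequally and may have made part of it. Of 646 genes 2-fold apart within spike-in libraries, 65.9% lay on the same side within low-rRNA libraries, and of those chosen in low-rRNA libraries 78.2% of 87 higher and 69.1% of 81 lower genes did so within spike-in libraries, all between the limits set for either reading. Of the pooled genes 26 of 129 higher and 16 of 151 lower were 2-fold apart in both sets, so genotype and library set cannot be told apart for most of these genes. Nlrp14 was lower in both sets (-3.07 and -4.71), and an effect of the genotype on the remaining genes stays open and untested.

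A second pattern is the lower zygotic-class share in KO 2-cell samples. Dilution by retained maternal RNA might lower every share, but per spike-in count the zygotic-class median was still -1.20, which argues against dilution alone if each library received equal spike-in amounts, a point the labels do not state. A single dilution factor is argued against too, as 57.6% of 594 quiet zygotic-class genes lay within 2-fold of their common ratio, against 95.8% between odd- and even-numbered WT samples. Libraries without a paternal genome are argued against by the lowest paternal share of zygotic-class counts in a KO sample, 13.1%. Slower development or weaker activation in embryos of KO mothers stays open and untested, and WT replicate 8 shows that low shares occur in WT too.

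The last pattern is the genes lower or without counts in cultured epiblast. Depth is argued against, since thinned E6.5 libraries still detected 13064 genes or more. Few starting molecules remain possible, because 2.43% of genes at 50 CPM or more in one IVC library had no count in the other, a value between the limits set for either reading. A different selection of RNA is consistent with the histone genes, whose median of -8.72 over 57 genes lay below matched lists (-1.88 to -0.44), but without Rn45s and histone genes 2734 genes were still lower, so these genes are not the whole pattern. Culture itself, embryonic stage, which the labels do not give for IVC, and a differing library protocol cannot be told apart, and all stay open.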

How the results depend on the processing

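Alternatives by library set, spike-in counts, single oocytes or 2-cell samples left out (named genes too), and Rn45s or histone genes left out were chosen after the result was seen, and the rest were fixed earlier. For the counts and values below that changed with the scaling, the weight of cells, the library set or the test, the cause was not tested, while other limits on low counts change which genes are tested. The planned paternal shares without genes of paternal signal in oocytes and without X and Y genes were not run, since the oocyte columns are not split by allele and gene positions are missing.

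In oocytes, the genes higher and lower in KO numbered 334 and 260 with equal weight per cell, 679 and 641 by medians over cells, 561 and 595 from 1 CPM, 33 and 47 from 50 CPM, and 600 and 235 in spike-in libraries. With the mean of both library sets 48 were lower. Without each library in turn they ran from 104 to 285 and from 116 to 228, and higher genes numbered 234, 285, 194 and 228 without WT replicates 1, 2, 3 and 14, with 228 lower without WT replicate 2. TMM, DESeq2 factors and totals without Rn45s kept both counts within 1.5 times. Lists outside their random lists numbered 2 with equal weight, 2 with DESeq2 factors, 4 by medians (a single factor moves every gene and random list alike, so DESeq2 differs by the redraw alone), 2 within spike-in libraries (cell cycle and stress response) and 2 within low-rRNA libraries (NLRP and cumulus markers), 3 by the mean of sets and 2 without WT replicate 14. Zfp770 changed sides in low-rRNA libraries (0.27). Nlrp14 was at -4.14 with equal weight, at -3.07 in spike-in and -4.71 in low-rRNA libraries, and at -4.39 to -3.71 without each library, the last without WT replicate 14.

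In 2-cell samples, 1397 genes were higher with TMM, 1520 with DESeq2 factors, 777 by medians and 2493 by spike-in counts, where 1454 were lower. From 1 CPM the counts were 1035 and 5361, and from 50 CPM 273 and 978. Without each library they ran from 397 to 981, the last without WT replicate 8, and from 2445 to 3187. By medians the p53 list came to lie within its random lists (percentile 6.41) and zygotic genome activation outside (-0.73, percentile 1.84). Nlrp14 was at -2.28 with equal weight, -1.57 with TMM, and -2.27 to -1.90 without each library.

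Between stages, 2249 genes were higher and 2758 lower with TMM, 2171 and 2927 with DESeq2 factors, and 1329 and 785 from 50 CPM, while 7189 were higher from 1 CPM. Without each library they ran from 3374 to 3792 and from 1192 to 1407. Lists outside their random lists numbered 9 by medians, where ribosome biogenesis, the stress response, oxidative phosphorylation and imprinted genes joined. Against spike-in oocytes alone they numbered 7, but oocyte transcripts and the NLRP list left and ribosome biogenesis, the stress response, cumulus markers and imprinted genes joined. With equal weight and without WT 2-cell replicate 8 ribosome biogenesis and imprinted genes joined, and without WT oocyte replicate 14 cumulus markers did. Mos and Plat changed sides against spike-in oocytes (0.89 and 1.53).

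The zygotic-class median was -2.20 with odd and even numbers exchanged, -1.30 at 2-fold, -1.97 with equal weight, -1.65 with TMM, -1.20 by spike-in counts and -1.80 with classes chosen against spike-in oocytes, and -2.41 to -1.54 without each library. The decay-class median was 0.67, 0.49, 0.84, 0.93, 1.35 and 0.77 in the same order, and 0.58 to 1.29 without each library; -2.41 and 1.29 are those without WT replicate 8. Neither class changed direction under these alternatives. The paternal share by medians over samples was 17.8% in WT and 3.02% in KO, without the 10 most counted genes 16.3 and 3.32%, and without each library 13.3 to 18.2% and 2.48 to 3.21%.

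In epiblast, 965 genes were higher and 631 lower without a filter, and 1729 were lower with 5 CPM. A replicate block, which the labels do not justify, gave 893 and 361. Without each library they ran from 612 to 2880 and from 118 to 5476: 612 and 125 without E6.5 replicate 1, 648 and 118 without E6.5 replicate 2, 2880 and 4997 without IVC replicate 1, and 2863 and 5476 without IVC replicate 2, the lone library being assumed to vary like the other group. Within 1.5 times both counts lay DESeq2 factors (1299 and 2808), upper-quartile factors (1414 and 2698), the DESeq2 test (1897 and 3006), limma-voom (1145 and 2490), thinning (1394 and 2672) and glmTreat (1113 and 2292). Prl4a1 missed the threshold with limma-voom (adjusted p = 0.0679) and Hspa1b without a filter (0.0635), with 5 CPM (0.0614) and with glmTreat (0.0546). With the block Prl4a1 (0.0575), Pfpl (0.058) and Fabp1 (0.0619) missed it. Trophoblast markers passed camera with 5 CPM (adjusted p = 0.00594). With estimated correlation camera passed 0 lists (2 at an unadjusted p under 0.05) and with fry 16, where primordial germ cell genes (adjusted p = 0.00104) and cholesterol synthesis (0.0097) changed direction, and without each library 2 to 8 lists passed. Thinned to 10241401 counts, the IVC libraries detected 8371 and 8990 genes and the E6.5 libraries 13064 and 13395.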

Other observations

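All tests in this part were chosen after the result was seen.

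Within the zygotic class, transcripts of the genome activation list were set beside the others in KO 2-cell samples, and the difference between them was not tested. Of zygotic-class genes under 1 CPM in oocytes, 18 belong to the fixed list of genome activation transcripts and 576 do not. The median ratio of KO to the even-numbered WT samples was -0.61 for the 18 and -2.39 for the others. Within single samples, the log2 ratio of the 18 to the others was -3.62 in WT (-3.80 to -2.43, with the odd-numbered samples that had chosen the class) and -2.32 in KO (-2.78 to -1.74), with overlap. The 18 went both ways: Zscan4a (0.66), Zscan4f (0.49), Usp17ld (0.69) and Usp17la (0.60) were above WT level, Usp17lc (-0.06) and Usp17lb (-1.35) of the same family were not, and Tdpoz2 (-4.37), Obox6 (-4.01), Pramel6 (-3.04) and Pramel7 (-3.00) were far below it. These members were singled out after their values were seen.

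Of 49 genes apart between KO and WT oocytes in both library sets, Nlrp14 included, 34 lay on the same side at the 2-cell stage, 15 of them 2-fold. Another 15 lay on the other side, 3 of them 2-fold. No background share was taken. Among all genes, 2658 were at least 2-fold lower and 502 higher at the 2-cell stage, and these sides depend on the scaling. The genes named here were chosen after their values were seen. Ddx60 was at -1.69 and -2.79 in the oocyte sets and at -2.80 in 2-cell samples, Bhlhe41, a clock repressor, at -2.17, -1.64 and -2.10, and Tnfsf11, the cytokine RANKL, at -1.56, -1.73 and -1.31. On the higher side, Prickle3 was at 1.81, 1.65 and 2.33 and Usp11, a deubiquitinase, at 1.57, 1.10 and 1.74. The 3 that were higher in both oocyte sets and at least 2-fold lower at the 2-cell stage were Rnf6 (-2.89), Cul3 (-2.82) and Cd9 (-1.62).

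Placental hormone genes in cultured epiblast might come from trophoblast giant cells, a hypothesis formed and tested after the result was seen. Of 15 giant cell markers written down before the test, 6 could be tested. Of these 1 was higher past the threshold and 2 were lower, Flt1 (-7.37 by counts, -10.42 to -5.51) and Ada, with no count in IVC and at least 46.8-fold lower. Most markers could not be tested, and 2037 tested genes had no count in IVC. The markers therefore cannot decide the hypothesis, which stays open. Not past the threshold were Mmp9, with 2 counts at E6.5, at 6.37 by counts (4.47 to 9.44, edgeR adjusted p = 0.0577), Adm (-1.37) and Gata2 (-0.21). The marker higher past the threshold, Prl4a1, is itself one of the hormone genes that raised the question, so it adds no separate evidence, and 1 of the 15 stands in another list. The markers summed to 35.9 and 162 CPM in IVC and 39.7 and 35.1 CPM at E6.5, where 4 of them reached 1 CPM in both libraries. Prl3d1, the most abundant hormone gene, stands in the trophoblast list and was not among the 15 markers. It reached 6254 and 6259 CPM in IVC.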
